A study of Drosophila melanogaster with 18 samples.

How the data were processed

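Targeted DamID records where a protein sits on chromatin. A bacterial DNA adenine methyltransferase (Dam), alone or fused to a chromatin protein, is expressed in chosen cells and methylates GATC sites near the places it reaches, and the methylated DNA is released, amplified and sequenced. Per the labels, the fly transgenes were driven by Eyeless-Gal4, which acts in the eye-antennal disc, under a temperature-sensitive Gal80 repressor. Per the labels, eggs were laid at 25 °C, larvae were kept at 18 °C for 4 days and were moved to 29 °C for 24 hours before dissection. The fusions carried Scalloped (Sd, the TEAD-family DNA-binding protein of the Hippo pathway), Yorkie (Yki, the coactivator that the Hippo kinases restrain) or Jun-related antigen (Jra, the Jun subunit of AP-1 downstream of JNK). The labels do not say whether replicates were separate crosses, animals or pools, so the p-values given here may measure technical spread.

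The authors' deposited count table gave whole-number read counts for 18 libraries at 767321 ends of GATC sites, each end on its own strand, of which 634883 held a read. The submitters' processing notes named Subread, featureCounts, edgeR, bedtools and the dm6 genome build, and versions were not given in the sources used here. The authors' deposited peak lists, 1 per fusion, gave each peak a log2 fold change and a p-value, with the gene starts within 5 kb. These peak scores and folds are the authors' own. Which Dam libraries they rest on was not given in the sources used here. They correlated best with folds against Set 3 for Dam-Jra (r = 0.949), Set 2 for Yki-Dam (0.928) and all 9 Dam libraries for Dam-Sd (0.933, and 0.757 for Set 1). Whether peaks were called per library or on pooled libraries was not given in the sources used here.

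Counts were summed over gene windows, each the span of a gene in the RefSeq table with 1 kb on both sides. There were 14206 windows, 13946 of protein-coding genes and 260 of microRNA genes, with a median of 32 ends each. Of these windows, 89.8% shared ends with another window, so a change in 1 window can belong to its neighbour. Libraries were scaled by trimmed mean of M values (TMM, factors 0.56 to 1.62), and windows or ends with low counts were left out by filterByExpr in edgeR with a minimum count of 10. All 18 libraries were fitted together as 6 groups in edgeR 4.0.16 (R 4.3.3) with 12 residual degrees of freedom. Groups were compared by the quasi-likelihood test with Benjamini-Hochberg adjustment over 14090 windows or 394539 ends, and an adjusted p below 0.05 was called. Standard errors (SE) are the size of the log2 fold change over the square root of F.

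Dam-Sd was compared with the Dam libraries of Set 1 and Yki-Dam with those of Set 2, as the titles place them. The titles place Dam-Jra in Set 1 and name another set of Dam libraries, Set 3, with no fusion of its own. Dam-Jra was therefore compared with the mean of the 3 Dam sets, and values against Set 3 alone are given for the fixed genes, the gene lists, the highest and lowest windows and the counts. Differences between fusions are differences of these fold changes.

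Replicate numbers paired Dam-Sd with Dam of Set 1. The correlations across windows of their deviations from the group means were 0.557, 0.373 and 0.371 for equal numbers and −0.510 to 0.239 for unequal ones. Yki-Dam paired less clearly with Dam of Set 2 (0.616, 0.385 and 0.310 against −0.526 to 0.365). There Yki-Dam replicate 3 correlated more with Dam replicate 2 (0.365) than with Dam replicate 3 (0.310). Dam-Jra paired with neither Set 1 (−0.238, −0.027 and −0.082) nor Set 3 (0.099, −0.093 and 0.065). Values from fits with the replicate number as a block stand beside a result where they ended a call or moved a count by over 1.5 times.

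Gene lists of 11 to 34 measured members were written down for Hippo pathway targets, Hippo pathway components, JNK pathway and AP-1 targets, JNK pathway components, epithelial polarity and junctions, actomyosin and cell shape, eye-antennal specification, cell cycle and growth, Notch, EGFR and JAK-STAT signalling, ribosomal proteins and chemosensory receptors. Markers of neurons, glia, haemocytes, muscle, fat body and germline stood for other cells that a dissected disc could hold and for genes not used in it. Some lists share members, so their results are not independent. Both JNK lists held puc, kay, Jra, egr, grnd and wgn, and both Hippo lists held ex, kibra, wts, Mer and jub. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 17 lists, and again with an estimated correlation. The genes named are sd, yki, Jra, ex, Diap1, mir-ban, puc and Mmp1, and up to 4 members of each list with the smallest p. The 8 highest and 4 lowest called windows of each comparison with above-median signal and separated libraries are named too. The lists, comparisons, named genes and most of the alternatives were chosen before the data were examined.

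Peak overlaps were counted at 1 bp or more and compared with 1000 circular shifts of 1 list along the chromosomes. Genes of the peak lists were matched by gene identifier and compared by Fisher's exact test against 17684 RefSeq genes on the same chromosomes. Motif searches and exon or intron locations were not analysed here, since they need the genome sequence and gene structures, which were not used here. In their place, ends inside each fused gene were compared with ends in the 5 kb around it, and peaks were placed by the gene starts the authors listed.

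The test was tried on counts simulated from the fitted spread, with 200 changed windows. All other windows had the same mean in every library, while 42.3% to 69.0% of the real windows were called. The shares of false calls below may therefore not carry over to the real fits. Changes of 4-fold were called in 100% (Dam-Sd), 98.7% (Yki-Dam) and 100% (Dam-Jra) of changed windows. Changes of 2-fold were called in 61.3%, 54.7% and 82.7%, and 3.39%, 3.51% and 5.56% of calls were false. At single ends 4-fold changes were called in 21.3%, 29.3% and 53.3% of changed ends, and 4.48%, 1.59% and 11% of calls were false. Reads are PCR copies without molecular identifiers, so limits drawn from counts cover counting error only, and a count of 0 allows up to 3 counts.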

Results

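Chromatin profiles of the Hippo pathway proteins Scalloped and Yorkie and of the JNK pathway protein Jun-related antigen were recorded by Targeted DamID in eye-antennal discs, the larval tissue that forms the eye and antenna, in early L3 larvae. The 18 libraries formed 6 groups with 3 replicates each, Dam alone in Sets 1, 2 and 3 and the fusions Dam-Sd, Yki-Dam and Dam-Jra. Libraries held 21.4 to 41 M counted reads (M, reads divided by 1e6). The Dam libraries held 26.2 to 35.7 M in Set 1, 21.4 to 27 M in Set 2 and 29.7 to 39.8 M in Set 3. Dam-Sd libraries held 27.6 to 36.9 M, Yki-Dam libraries 30.6 to 41 M and Dam-Jra libraries 34.0 to 36.8 M. Reads were more concentrated in the fusions, where the 1% of ends with the most reads took 47.4% ± 5.13 in Dam-Sd, 44.6% ± 3.34 in Yki-Dam and 42.5% ± 0.244 in Dam-Jra (mean ± SD, n = 3). The Dam sets gave 22.1% ± 4.53, 28.4% ± 4.15 and 33.6% ± 1.02.

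On the first 2 principal components of the gene windows, replicates lay close to each other within Dam-Jra, within Yki-Dam and within Dam of Set 3. These groups lay apart from one another, and the Dam-Sd libraries spread widely along the first component. Dam in Sets 1 and 2 overlapped on the first (−72.6 to −38.8 and −83.2 to −67.9) and parted on the second (12.8 to 32.5 and −6.83 to 3.56). Dam sets differed from each other, with 1610 called windows between Sets 1 and 2, 4045 between Sets 1 and 3 and 4913 between Sets 2 and 3.

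**Figure D1:**
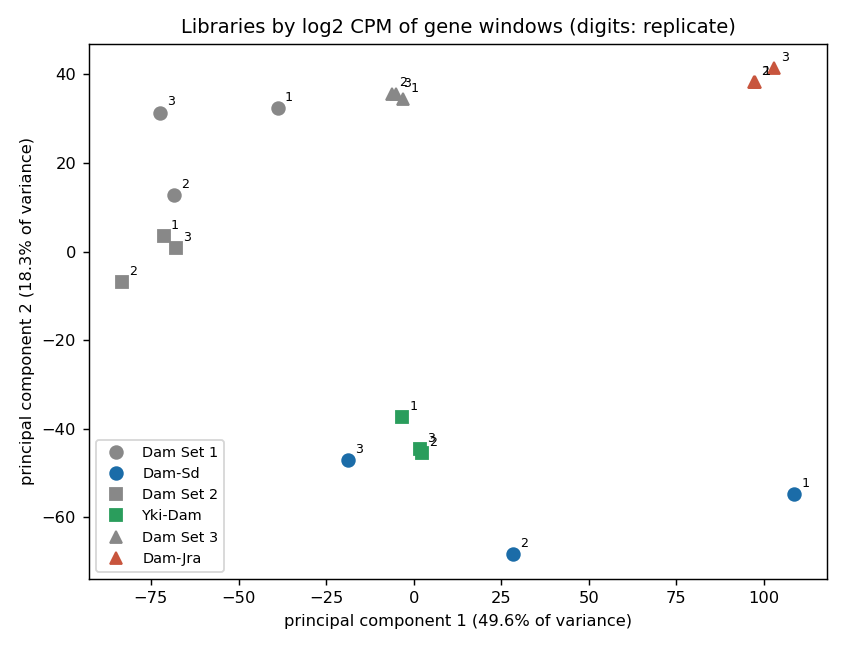
Each point is 1 library placed by the first principal component (x axis, 49.6% of the variance) and the second (y axis, 18.3%) of the log2 CPM of its gene windows, with the replicate number beside it. The Dam-Sd libraries sit at 108.5, 28.3 and −18.7 on the x axis, farther apart than the 3 libraries of any other group.

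Dam-Sd was compared with Dam of Set 1 to find where Scalloped lies in the disc. Known Hippo pathway target genes were among the windows that gained most. The window of mir-ban (3L:642208-642288), the bantam microRNA that promotes growth, rose 14.9-fold, from 43.1 ± 10.02 to 642 ± 316 CPM (TMM-scaled reads of the window per 1e6 reads of the library, mean ± SD, n = 3; log2 fold change 3.90 ± 0.36 SE, adjusted p = 1.19e-07). The window of ex (expanded, 2L:431227-448701), an upstream regulator of the pathway, rose 10.7-fold, from 385 ± 86.8 to 4107 ± 1787 (log2 3.41 ± 0.30, adjusted p = 9.18e-08). Diap1 (3L:16038410-16051034), which inhibits caspases, rose 8.03-fold (log2 3.01 ± 0.29, adjusted p = 1.45e-07), and kibra, another upstream regulator, rose 9.30-fold (log2 3.22 ± 0.26, adjusted p = 4.8e-08). The gene of the fused protein, sd (X:15804370-15827682), rose 3.18-fold (log2 1.67 ± 0.24, adjusted p = 8.84e-06). The JNK phosphatase gene puc (3R:8105332-8122294) rose 3.10-fold (log2 1.63 ± 0.22, adjusted p = 3.95e-06), and the Jun gene Jra rose 1.56-fold (log2 0.64 ± 0.18, adjusted p = 0.00429). The window of yki had log2 −0.44 ± 0.23 and did not pass (adjusted p = 0.115), but passed, with the same sign, without Dam replicate 2 of Set 1 (−0.59) or Dam-Sd replicate 3 (−0.67), without the flanks and with library size as the only scaling. The matrix metalloproteinase gene Mmp1 rose 1.51-fold (log2 0.60 ± 0.21, adjusted p = 0.0177), with overlapping libraries.

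The highest windows in Dam-Sd were Brd, a Bearded-family gene of Notch signalling (log2 4.03 ± 0.40), mir-ban, CG42807 (3.81 ± 0.37), CG46304 (3.77 ± 0.33) and the histone variant gene His2Av (3.68 ± 0.39). They were followed by mir-954 (3.61 ± 0.29), Acp26Ab (3.60 ± 0.34) and Ugt302C1 (3.58 ± 0.36). The lowest were E(Pc) (Enhancer of Polycomb, −2.31 ± 0.27), the kinesin gene Klp68D (−2.30 ± 0.23), l(2)k09022 (−2.28 ± 0.24) and CG10948 (−2.24 ± 0.27). Without the 1 kb flanks, the His2Av window fell to 0.22 and was not called.

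Of 23 Hippo pathway targets, 17 were higher in Dam-Sd and 6 did not pass (median log2 1.87, camera adjusted p = 1.23e-11, adjusted p = 0.172 with an estimated correlation). Of 32 JNK pathway and AP-1 targets, 30 were higher, among them the zinc-finger gene chinmo (2.65 ± 0.28) and the stress sensor gene Keap1 (2.09 ± 0.23), and 2 did not pass (median 1.45, camera adjusted p = 2.74e-12, adjusted p = 0.172 with an estimated correlation). Eye-antennal specification genes were higher in 27 of 31 cases and lower in 1, with the homeobox genes toe (1.99 ± 0.20) and Lim1 (2.35 ± 0.25) as examples (median 1.61, camera adjusted p = 2.74e-12, adjusted p = 0.172 with an estimated correlation). Of 23 Notch, EGFR and JAK-STAT signalling genes, 16 were higher and 4 lower, led by the Notch target E(spl)m8-HLH (3.29 ± 0.25) and the EGFR pathway repressor aop (3.07 ± 0.29) (median 1.91, camera adjusted p = 9.48e-08, adjusted p = 0.172 with an estimated correlation).

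Smaller shifts were seen in Hippo pathway components (12 higher and 5 lower of 30, with Fbxl7 at 2.92 ± 0.29 and the kinase gene wts at 1.83 ± 0.19, camera adjusted p = 0.00445, adjusted p = 0.172 with an estimated correlation). JNK pathway components gave 12 higher and 5 lower of 21, with Traf4 at 1.90 ± 0.20 and Src42A at 2.13 ± 0.23 (camera adjusted p = 0.00358, adjusted p = 0.215 with an estimated correlation). Epithelial polarity and junction genes gave 21 higher and 5 lower of 34, with cno at 2.67 ± 0.27 and sdt at 1.67 ± 0.23 (camera adjusted p = 0.004, adjusted p = 0.361 with an estimated correlation). Actomyosin and cell shape genes gave 17 higher and 4 lower of 33, with pbl at 2.12 ± 0.21 and alpha-Spec at −2.14 ± 0.22 (camera adjusted p = 0.00111, adjusted p = 0.368 with an estimated correlation). Cell cycle and growth genes gave 12 higher and 7 lower of 28, with InR at 2.10 ± 0.21 and E2f1 at 2.74 ± 0.29 (camera adjusted p = 0.0297, adjusted p = 0.475 with an estimated correlation). Glial markers gave 6 higher and 3 lower of 11, with alrm at 1.64 ± 0.19 and pnt at 2.23 ± 0.28 (camera adjusted p = 0.0272, adjusted p = 0.172 with an estimated correlation and 0.0504 with the replicate block). Chemosensory receptor genes, which mature sense organs use, gave 3 higher and 11 lower of 30, with Gr93a at 2.29 ± 0.21 and Ir25a at −2.11 ± 0.23 (camera adjusted p = 0.0204, adjusted p = 0.479 with an estimated correlation).

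Lists that did not pass in Dam-Sd were ribosomal proteins (8 higher, 11 lower, camera adjusted p = 0.863), neurons (4 and 2, 0.863), haemocytes (5 and 9, 0.863), fat body (3 and 7, 0.863), muscle (4 and 3, 0.801) and germline (3 and 4, 0.801). The fat body list had a median of 0.10 but a mean of −0.18 and a downward test. Adjusted over the list alone, the counts were 17 higher and 1 lower for Hippo pathway targets, 31 higher for JNK pathway and AP-1 targets, 17 and 4 for signalling, 6 and 9 for haemocytes, 3 and 2 for neurons and 2 and 4 for germline. The other lists had the same counts as over all windows.

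Over all 14090 tested windows, 3682 were higher and 4264 lower in Dam-Sd than in Dam, and of 394539 tested ends 51372 were higher and 61402 lower. More windows were higher than lower with DESeq2 size factors (4150 and 3535), DESeq2's Wald test (4159 and 3622) and adjusted p below 0.01 (3090 and 3086). More ends were higher with adjusted p below 0.01 (31835 and 29070), the mean of the 3 Dam sets as control (60290 and 59770) or without Dam-Sd replicate 1 (34800 and 34366) or 2 (41080 and 36194). With library size as the only scaling the median window moved to −1.24, from −0.17, and 11% of called windows were higher (46.3% with TMM), with Jra at −0.44, Mmp1 at −0.50 and the calls of the cell cycle, chemosensory, epithelial and glia lists lost. With that scaling 5 lists passed with an estimated correlation, among them Hippo pathway targets (adjusted p = 0.00569). The Mmp1 call was lost without Dam replicate 2 or 3 of Set 1 or Dam-Sd replicate 1 (0.52, 0.50 and 0.36) and with only the comparison's libraries fitted (0.60). The ends called were 73812 without that Dam replicate 3 and 69166 without Dam-Sd replicate 1.

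**Figure D2:**
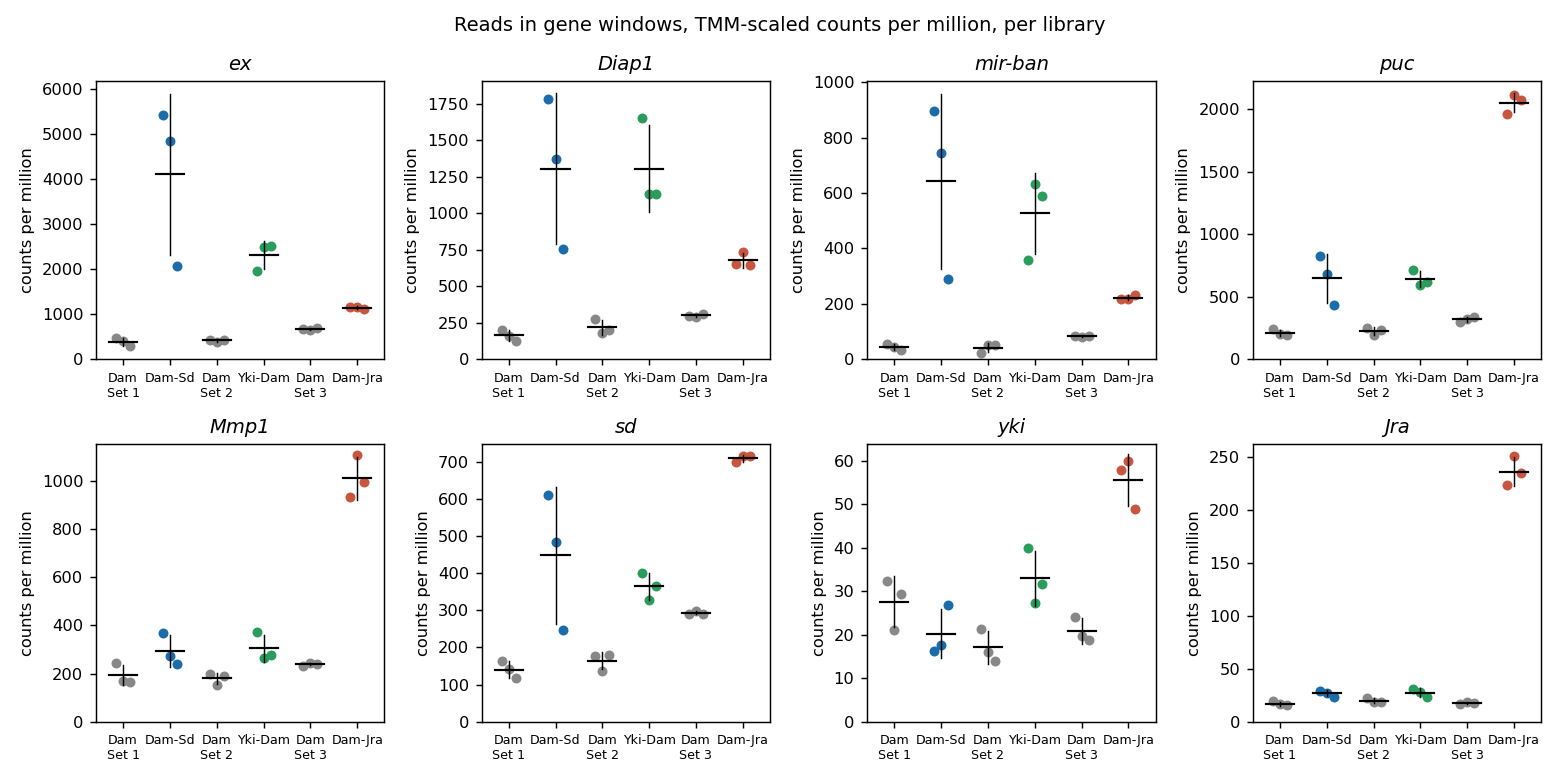
Points are TMM-scaled CPM in 8 gene windows (y axes, linear) for the 3 libraries of each group (x axes), with bars at the mean and lines for 1 SD. Dam-Sd and Yki-Dam gave the highest means for ex (4107 in Dam-Sd) and Dam-Jra for puc, Mmp1, sd, yki and Jra.

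Yki-Dam was compared with Dam of Set 2 to find where Yorkie lies. Its highest window was mir-ban, which rose 12.7-fold (log2 3.66 ± 0.36 SE, n = 3, adjusted p = 7.6e-07). The windows of kibra (7.0-fold, log2 2.81 ± 0.26, adjusted p = 5.07e-07), Diap1 (6.02-fold, 2.59 ± 0.28, adjusted p = 1.48e-06) and ex (5.62-fold, 2.49 ± 0.29, adjusted p = 3e-06) rose with it. The gene of the partner protein, sd, rose 2.22-fold (1.15 ± 0.24, adjusted p = 0.00084), and puc rose 2.85-fold (1.51 ± 0.22, adjusted p = 2.63e-05). The gene of the fused protein, yki (2R:24065975-24068485), rose 1.92-fold (0.94 ± 0.23, adjusted p = 0.00338), Mmp1 rose 1.69-fold (0.76 ± 0.21, adjusted p = 0.00664) and Jra rose 1.37-fold (0.45 ± 0.18, adjusted p = 0.0448).

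After mir-ban, the highest windows in Yki-Dam were CG14506 (3.25 ± 0.29), the microRNA genes mir-275 (3.17 ± 0.47) and mir-305 (3.16 ± 0.42), His2Av (3.11 ± 0.38), CG15625 (3.03 ± 0.28), CG42807 (2.98 ± 0.36) and CG32462 (2.96 ± 0.28). The lowest were CG31077 (−1.92 ± 0.28), CG31787 (−1.81 ± 0.31), tobi (−1.72 ± 0.23) and Aptx (−1.45 ± 0.19). Without the flanks His2Av turned to −0.34.

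Of 23 Hippo pathway targets 19 were higher and 1 lower in Yki-Dam, with wts at 1.80 ± 0.19 (median 1.45, camera adjusted p = 7.74e-15, adjusted p = 0.131 with an estimated correlation). JNK pathway and AP-1 targets were higher in 27 of 32 cases, with chinmo at 2.22 ± 0.27 and GstD1 at 1.74 ± 0.22 (median 1.17, camera adjusted p = 7.55e-14, adjusted p = 0.131 with an estimated correlation). Eye-antennal specification genes were higher in 26 of 31 and lower in 1, with Lim1 at 1.95 ± 0.24 and toe at 1.55 ± 0.20 (median 1.33, camera adjusted p = 2.03e-14, adjusted p = 0.131 with an estimated correlation). Signalling genes were higher in 16 and lower in 2 of 23, with E(spl)m8-HLH at 2.71 ± 0.24 and aos, a secreted EGFR inhibitor, at 1.92 ± 0.24 (median 1.45, camera adjusted p = 3.6e-09, adjusted p = 0.131 with an estimated correlation).

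Actomyosin and cell shape genes gave 22 higher and 1 lower of 33 (cher 1.73 ± 0.22, pbl 1.62 ± 0.21, camera adjusted p = 1.86e-06, adjusted p = 0.133 with an estimated correlation), and cell cycle and growth genes 14 and 1 of 28 (InR 1.70 ± 0.21, E2f1 2.10 ± 0.28, camera adjusted p = 4.69e-05, adjusted p = 0.131 with an estimated correlation). Epithelial polarity and junction genes gave 21 and 2 of 34 (cno 1.97 ± 0.26, scrib 1.54 ± 0.24, camera adjusted p = 6.96e-05, adjusted p = 0.131 with an estimated correlation). Hippo pathway components gave 15 and 3 of 30 (Fbxl7 2.27 ± 0.29, camera adjusted p = 0.000163, adjusted p = 0.131 with an estimated correlation), and JNK pathway components 13 and 1 of 21 (Traf4 1.84 ± 0.20, kay 1.70 ± 0.23, camera adjusted p = 0.00015, adjusted p = 0.131 with an estimated correlation). Chemosensory receptors gave 1 higher and 13 lower of 30 (Gr93a 2.04 ± 0.21, Or83a −1.12 ± 0.26, camera adjusted p = 0.00936, adjusted p = 0.387 with an estimated correlation).

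Neurons (1 higher and 9 lower, camera adjusted p = 0.0528), ribosomal proteins (9 higher, 0.0557), glia (4 and 2, 0.193), muscle (5 higher, 0.193), germline (2 and 4, 0.208), haemocytes (6 and 4, 0.537) and fat body (3 and 4, 0.537) did not pass in Yki-Dam. The haemocyte list had a median of −0.36, a mean of 0.01 and an upward test. Adjusted over the list alone, the counts were 15 higher and 1 lower for cell cycle, 1 and 14 for chemosensory receptors, 22 and 2 for epithelial genes and 27 and 1 for eye-antennal genes. They were 28 higher for AP-1 targets, 17 and 3 for signalling, 1 and 10 for neurons, 5 and 2 for glia, 3 and 5 for fat body and 8 higher for ribosomal proteins.

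Of the tested windows 3094 were higher and 2861 lower in Yki-Dam, and of the tested ends 35332 were higher and 28299 lower. The ends were 95916 in both directions with the replicate block, and 31817 higher and 40076 lower with DESeq2 size factors. More windows were lower than higher without any 1 Yki-Dam library (2383 higher and 3917 lower, 2162 and 3198, and 2129 and 3046), with DESeq2 size factors (2872 and 3182), with the replicate block (3604 and 3875) and with the mean of the 3 Dam sets as control (3262 and 3304). With library size as the only scaling the median window moved to −0.94, from −0.13, and 10.8% of called windows were higher (52.0% with TMM). The balance of ends turned there, with 20965 higher and 111094 lower. The value of yki fell to 0.13, Jra to −0.36 and Mmp1 to −0.05 there, and the chemosensory call was lost. With that scaling 7 lists passed with an estimated correlation, among them Hippo pathway targets (adjusted p = 0.0011). The call of Jra was lost without any Yki-Dam library (0.20, 0.30 and 0.43), with DESeq2 size factors (0.43), with only the comparison's libraries fitted (0.50) or without Dam replicate 2 or 3 of Set 2 (0.42 and 0.39). That of Mmp1 was lost without Yki-Dam replicate 1 (0.44). The ends called were 36852 and 38825 without Yki-Dam replicates 2 and 3.

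**Figure D3:**
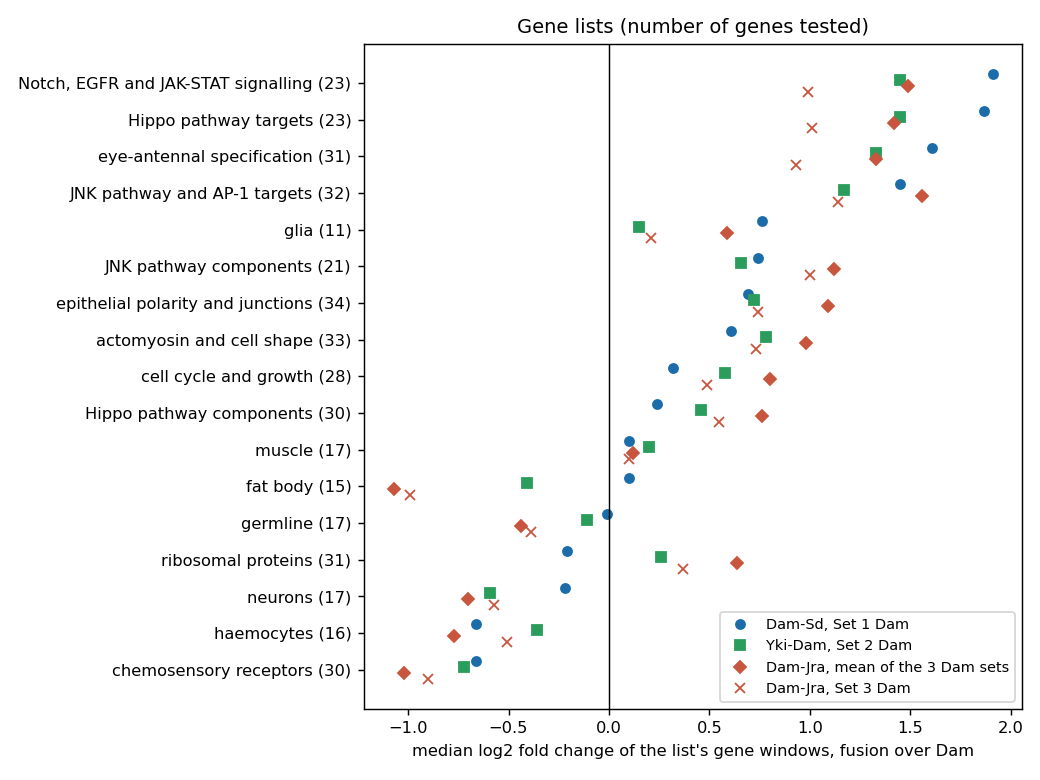
Each symbol is the median log2 fold change (x axis) of the gene windows of 1 list (y axis, with the number tested) in 1 comparison of a fusion with Dam. Hippo pathway targets lay at 1.87 in Dam-Sd, 1.45 in Yki-Dam and 1.42 in Dam-Jra, and chemosensory receptors lay below 0 in each.

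Dam-Jra was compared with the mean of the 3 Dam sets, and with Set 3 alone, to find where the AP-1 protein lies. The window of puc rose 8.32-fold (log2 3.06 ± 0.16 SE, n = 3, adjusted p = 3.4e-12, and 2.69 against Set 3). Ets21C, an ETS factor gene induced by JNK, rose 7.71-fold (2.95 ± 0.16, adjusted p = 9.92e-12, and 2.47), and Mmp1 (2R:24671294-24688184) rose 4.99-fold (2.32 ± 0.15, adjusted p = 1.07e-10, and 2.08). The Fos gene kay rose 5.13-fold (2.36 ± 0.17, adjusted p = 3.19e-10, and 2.14). The gene of the fused protein, Jra (2R:10096480-10098556), rose 13-fold (3.70 ± 0.12, adjusted p = 1.89e-15, and 3.75). Hippo pathway genes rose as well, mir-ban 4.21-fold (2.07 ± 0.25, and 1.44), sd 3.75-fold (1.91 ± 0.18, and 1.27), Diap1 3.09-fold (1.63 ± 0.20, and 1.18), yki 2.59-fold (1.37 ± 0.17, and 1.42) and ex 2.41-fold (1.27 ± 0.21, adjusted p = 2.58e-05, and 0.77 with adjusted p = 0.0257).

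Inside Jra, the median end had log2 2.93 in Dam-Jra, against −1.33 for ends in the 5 kb around the gene. The median end of sd had 0.34 inside and −0.58 around the gene in Dam-Sd and 0.81 and −1.08 in Dam-Jra, and that of yki 0.75 and 0.14 in Yki-Dam and 0.90 and 0.17 in Dam-Jra. The highest windows in Dam-Jra were RpLP0-like (4.36 ± 0.13), CaBP1 (4.18 ± 0.22), CG34299 (4.17 ± 0.15), CG4455 (3.74 ± 0.18), Jra, mir-4943 (3.49 ± 0.14), CG13894 (3.44 ± 0.17) and Ude (3.32 ± 0.18). The lowest were dpr21 (−3.08 ± 0.41), the serotonin receptor gene 5-HT1A (−2.91 ± 0.37), the dynein gene Dhc16F (−2.85 ± 0.22) and Nipped-A (−2.74 ± 0.40). Against Set 3 alone RpLP0-like had 4.14, CaBP1 4.19, CG34299 4.06, CG4455 3.57, mir-4943 3.38, CG13894 3.14, Ude 3.24, dpr21 −2.51, 5-HT1A −2.19, Dhc16F −2.45 and Nipped-A −2.38. Without the flanks RpLP0-like turned to −0.06.

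Of 32 JNK pathway and AP-1 targets, 31 were higher in Dam-Jra (median 1.56, camera adjusted p = 1.11e-15, adjusted p = 0.15 with an estimated correlation). Both JNK lists include Jra, the gene of the fused protein. JNK pathway components gave 15 higher and 2 lower of 21, with p38a at 2.03 ± 0.13 (median 1.12, camera adjusted p = 4.74e-08, adjusted p = 0.0987 with an estimated correlation), which fell to 0.33 without the flanks. Actomyosin and cell shape genes gave 24 and 3 of 33, with Act42A at 2.77 ± 0.12 and the ERM protein gene Moe at 2.83 ± 0.21 (median 0.98, camera adjusted p = 5.6e-08, adjusted p = 0.15 with an estimated correlation). Of 23 Hippo pathway targets 21 were higher and 1 lower, with CycB at 2.04 ± 0.16 and Myc at 1.87 ± 0.15 (median 1.42, camera adjusted p = 5.6e-08, adjusted p = 0.15 with an estimated correlation). Eye-antennal specification genes gave 28 and 1 of 31, with pnr at 2.26 ± 0.17 and toe at 1.73 ± 0.15 (median 1.33, camera adjusted p = 3.82e-10, adjusted p = 0.15 with an estimated correlation). Signalling genes gave 19 and 3 of 23, with E(spl)m8-HLH at 2.14 ± 0.17 and Socs36E, a JAK-STAT inhibitor, at 2.21 ± 0.21 (median 1.49, camera adjusted p = 1.13e-06, adjusted p = 0.15 with an estimated correlation). Against Set 3 alone 28 AP-1 targets were higher (median 1.14), 14 JNK pathway components higher and 1 lower (1.00) and 20 actomyosin genes higher and 1 lower (0.73). There 19 Hippo pathway targets were higher (median 1.01), 24 eye-antennal genes higher and 1 lower (0.93) and 18 signalling genes higher and 2 lower (0.99). These lists passed there (camera adjusted p of 1.05e-05 or less, adjusted p of 0.0999 or more with an estimated correlation).

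Epithelial polarity and junction genes gave 26 higher and 4 lower of 34 (vari 1.85 ± 0.16, shg 1.41 ± 0.15, camera adjusted p = 1.09e-05, adjusted p = 0.15 with an estimated correlation), and cell cycle and growth genes 18 and 2 of 28 (Rbf 1.62 ± 0.17, RnrS 1.30 ± 0.13, camera adjusted p = 0.000577, adjusted p = 0.15 with an estimated correlation). Hippo pathway components gave 20 and 4 of 30 (vers 1.34 ± 0.14, Tgi 1.78 ± 0.19, camera adjusted p = 0.000748, adjusted p = 0.143 with an estimated correlation). Ribosomal proteins gave 18 and 2 of 31 (RpL3 1.74 ± 0.12, RpS20 1.69 ± 0.14, camera adjusted p = 0.0164, adjusted p = 0.15 with an estimated correlation), and 9 and 2 against Set 3 (camera adjusted p = 0.0255, adjusted p = 0.198 with an estimated correlation). Chemosensory receptors gave 2 higher and 21 lower of 30 (Gr93a 2.14 ± 0.15, Orco −1.52 ± 0.21, camera adjusted p = 0.00761, adjusted p = 0.391 with an estimated correlation), and 2 and 12 against Set 3 (camera adjusted p = 0.0255, adjusted p = 0.442 with an estimated correlation). Against Set 3 epithelial genes gave 24 and 4, cell cycle genes 12 higher and Hippo pathway components 17 and 5 (camera adjusted p of 0.00123 or less, adjusted p of 0.165 or more with an estimated correlation). Glia (7 and 3, camera adjusted p = 0.0574), neurons (3 and 10, 0.0574), fat body (4 and 11, 0.3), germline (4 and 9, 0.349), haemocytes (5 and 9, 0.722) and muscle (6 and 5, 0.722) did not pass. Against Set 3 these gave 4 higher, 2 and 9, 3 and 9, 1 and 6, 5 and 5 and 4 and 2, and did not pass (camera adjusted p of 0.0674 or more). The muscle list had a median of 0.12, a mean of −0.02 and an upward test. Adjusted over the list alone, cell cycle gave 19 and 2, epithelial genes 27 and 4 and Hippo pathway components 21 and 4, and the other lists had the same counts as over all windows.

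Of the tested windows 4599 were higher and 5116 lower in Dam-Jra, and 3277 and 3808 against Set 3 alone. Called in the same direction against Set 1 and against Set 3 were 2987 higher and 3304 lower windows. Of the tested ends 79649 were higher and 85112 lower, 38509 and 30450 against Set 3 alone, and 33627 and 24590 against both candidate sets. With library size as the only scaling the median window moved to −1.03, from −0.10 (−0.79 from −0.14 against Set 3), and 15% of called windows were higher (47.3% with TMM). The balance of ends called against both candidate sets turned with that scaling, with 14795 higher and 77973 lower. There yki fell to 0.45, and the chemosensory and ribosomal calls were lost. With that scaling 8 lists passed with an estimated correlation, among them AP-1 targets (adjusted p = 0.00104). More ends were higher than lower without any 1 Dam-Jra library (68042 and 44322, 63698 and 38864, and 63578 and 35155, with totals of 102562 and 98733 without replicates 2 and 3), with adjusted p below 0.01 (59622 and 32391) and without the filter on low counts (81593 and 78076). It turned as well without Dam replicate 3 of Set 1, replicate 2 or 3 of Set 2 or any 1 of Set 3. The ends called against both sets were 37910, 28372 and 29217 without Dam-Jra replicates 1, 2 and 3 and 35685, 33611 and 38406 without Set 3 Dam replicates 1, 2 and 3.

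**Figure D4:**
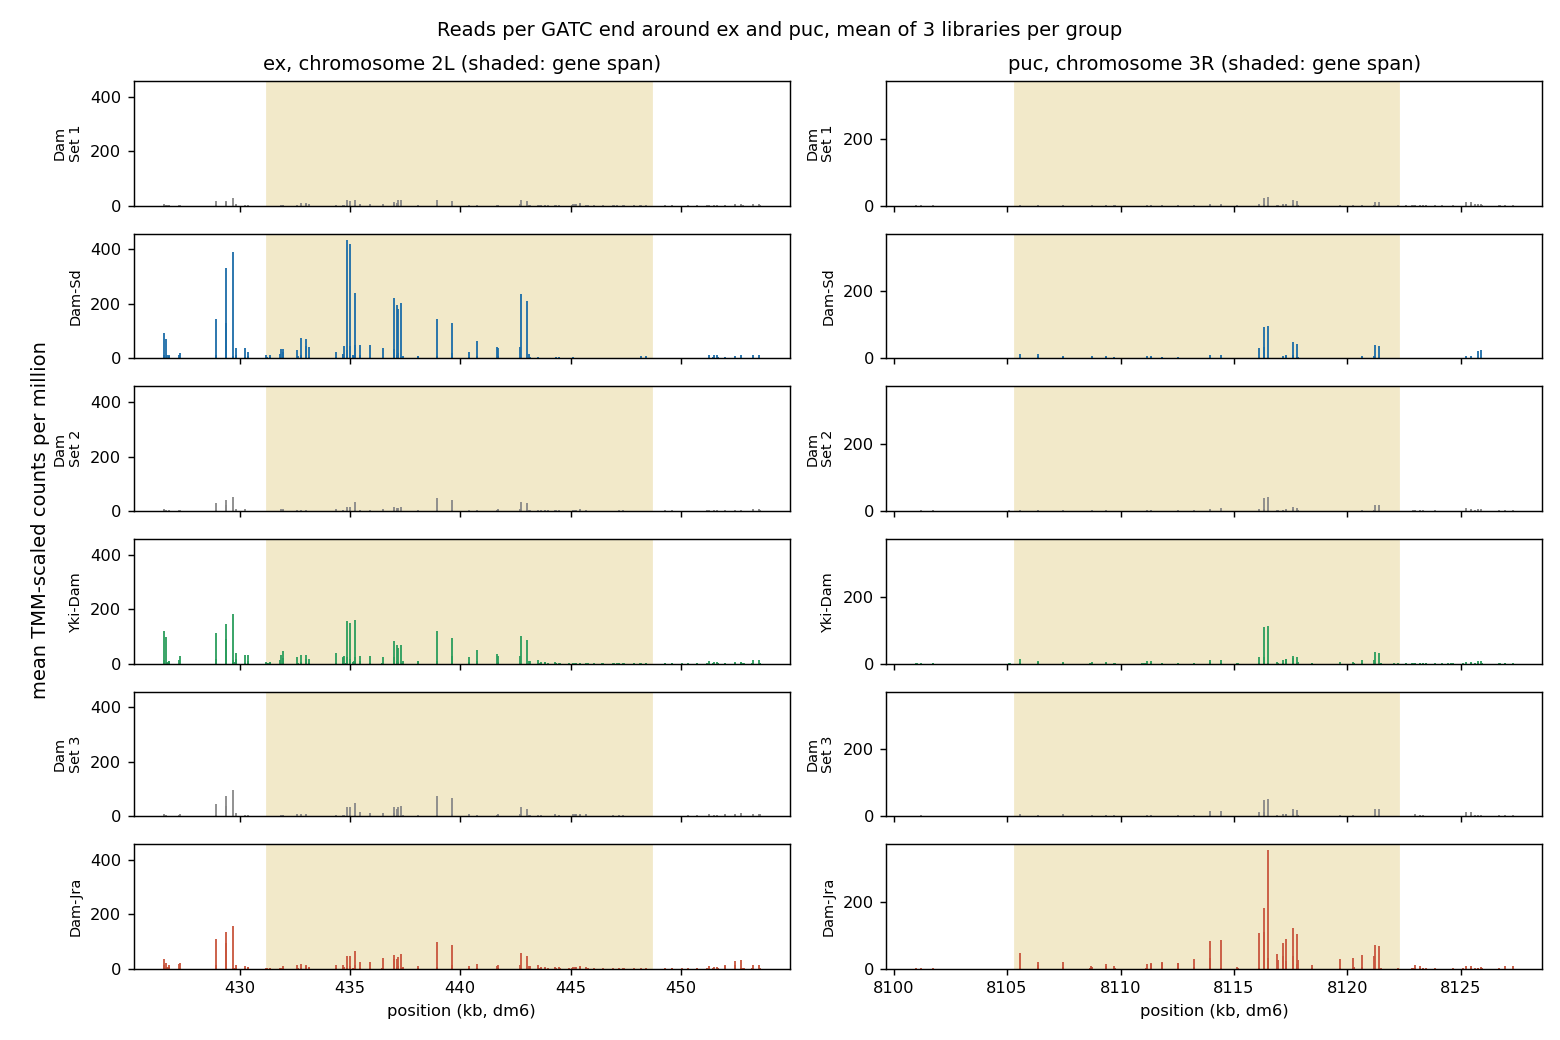
Vertical lines are the mean TMM-scaled CPM (y axes) of the 3 libraries of a group at each GATC end along ex on chromosome 2L and puc on 3R (x axes, position in kb, dm6, gene span shaded). The highest end in view for ex was 436 in Dam-Sd (2L:434869), where Dam of Set 1 had 19.9 and Dam of Set 3 had 32.45. For puc it was 355 in Dam-Jra (3R:8116500), where Dam of Set 3 had 50.6.

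Dam-Sd and Yki-Dam were compared to see where the DNA-binding protein and its coactivator part. Between them, yki was the only fixed gene that passed, with a log2 difference of −1.38 ± 0.33 (Dam-Sd minus Yki-Dam, n = 3, adjusted p = 0.0286). It is the gene of the protein fused in Yki-Dam, so its window can hold reads from that transgene. Other fixed genes differed by less, among them ex (0.92 ± 0.39, adjusted p = 0.167) and mir-ban (0.23 ± 0.47, adjusted p = 0.803). The glial gene alrm was higher in Dam-Sd (1.67, adjusted p = 0.00447), and RpL32 (−1.34, adjusted p = 0.011), RpL3 (−1.25, adjusted p = 0.0116) and the odorant-binding protein gene Obp19d (−1.49, adjusted p = 0.0145) were lower. The ribosomal proteins list had a median difference of −0.49 (4 lower of 31, camera adjusted p = 0.0271, adjusted p = 0.414 with an estimated correlation, 2 higher and 9 lower when adjusted over the list alone). In all, 197 windows were higher and 310 lower. The balance turned with the fusions compared directly (1239 and 932), with DESeq2 (816 and 434), without any 1 Dam-Sd library (321 and 189, 214 and 71, and 1732 and 884 for replicates 1, 2 and 3) and without any 1 Yki-Dam library (248 and 104, 150 and 124, and 100 and 92). With the replicate block 2050 windows passed, which held all 507. The count was 2616 without Dam-Sd replicate 3 and 285 without Dam-Sd replicate 2, 164 without Dam replicate 3 of Set 1, 882, 243 and 184 without Dam replicates 1, 2 and 3 of Set 2, and 274 and 192 without Yki-Dam replicates 2 and 3.

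Dam-Jra was set against Dam-Sd and Yki-Dam to see where the AP-1 and Hippo proteins part. Against Dam-Sd, puc was higher by log2 1.43 ± 0.25 (adjusted p = 0.000167), Mmp1 by 1.72 ± 0.24 (adjusted p = 1.53e-05) and yki by 1.81 ± 0.26 (adjusted p = 2.94e-05). Jra, the gene of the fused protein, was higher by 3.06 ± 0.19 (adjusted p = 1.26e-09), and its window can hold reads from the transgene. The windows of ex (−2.14 ± 0.33, adjusted p = 4.52e-05), mir-ban (−1.82 ± 0.38, adjusted p = 0.000907) and Diap1 (−1.38 ± 0.31, adjusted p = 0.00166) were lower. Of the 23 Hippo pathway targets 3 were higher, 10 lower and 10 did not pass, and the list did not pass (camera adjusted p = 0.222). It passed with Set 3 as the control (1 higher and 12 lower, camera adjusted p = 0.0171, adjusted p = 0.913 with an estimated correlation). Of the 32 JNK pathway and AP-1 targets 6 were higher and 6 lower than in Dam-Sd, and that list did not pass (median 0.02, camera adjusted p = 0.497). With Set 3 as the control 6 AP-1 targets were higher and 8 lower (median −0.40, camera adjusted p = 0.792). Against Yki-Dam, puc was higher by 1.55 ± 0.25 (adjusted p = 0.000165), Mmp1 by 1.56 ± 0.24 (adjusted p = 9.71e-05) and Jra by 3.25 ± 0.19 (adjusted p = 1.7e-09). There ex differed by −1.22 ± 0.32 (adjusted p = 0.00938), mir-ban by −1.59 ± 0.38 (adjusted p = 0.00514) and Diap1 by −0.96 ± 0.31 (adjusted p = 0.0271). The Hippo pathway target list gave 1 higher and 5 lower (camera adjusted p = 0.532, and 0.039 with Set 3, adjusted p = 0.98 with an estimated correlation). The AP-1 targets gave 10 higher and 0 lower (camera adjusted p = 0.00266, adjusted p = 0.69 with an estimated correlation), and 5 higher with Set 3 (camera adjusted p = 0.386). With Set 3 as the control each single gene named above passed in the same direction, and sd, higher than in Yki-Dam by 0.76 ± 0.27 (adjusted p = 0.0458), did not (0.13 ± 0.33, adjusted p = 0.848).

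In all, 2777 windows were higher and 2964 lower in Dam-Jra than in Dam-Sd (4138 in both directions with Set 3), and 1711 higher and 1791 lower than in Yki-Dam (1260 with Set 3, 5599 with the replicate block). Against Dam-Sd more were higher than lower with adjusted p below 0.01 (1868 and 1589), library size as the only scaling (3076 and 1879) or without Dam-Jra replicate 2 (2209 and 2183) or 3 (2228 and 2112). Against Yki-Dam more were higher with Set 3 (687 and 573), adjusted p below 0.01 (992 and 668), without the flanks (1413 and 1347) and without Dam replicate 3 of Set 2 (1502 and 1459) or of Set 3 (1624 and 1622). The balance turned as well without any 1 Dam-Jra library (1776 higher and 815 lower, 1603 and 715, and 1604 and 621 for replicates 1, 2 and 3) or any 1 Yki-Dam library (2088 and 1107, 1690 and 1026, and 1668 and 977). The totals were 2318 and 2225 without Dam-Jra replicates 2 and 3.

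The 3 profiles were compared window by window. Fold changes of Dam-Sd and Yki-Dam correlated across 14090 windows with Pearson r = 0.7727 and Spearman rho = 0.7386, and windows are not independent replicates. The values were 0.7071 and 0.7474 for Yki-Dam and Dam-Jra (r = 0.6625 with Set 3) and 0.5409 and 0.5828 for Dam-Sd and Dam-Jra (r = 0.4979 with Set 3). Among called windows, 2522 were higher in both Dam-Sd and Yki-Dam, where 808.5 were expected by chance, and 46 went opposite ways. Dam-Sd and Dam-Jra shared 2740 higher windows (1202 expected) with 599 opposite, and Yki-Dam and Dam-Jra shared 2542 (1010 expected) with 194 opposite. Higher in all 3 fusions were 2199 windows (263.9 expected), and lower in all 3 were 1478 (314.4 expected). Dam-Jra shares Dam libraries with the others, and the covariance was 0.757 with Dam-Sd and 0.7466 with Yki-Dam, against 0.01866 and 0.01873 in 20 simulations without any change. The simulations held no differences between the Dam sets, so they do not measure all that shared libraries can add. With Set 3 as the control, where no library is shared, the covariance was 0.5556 with Dam-Sd and 0.5577 with Yki-Dam.

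The authors' deposited peak lists held 5057 Dam-Sd, 3878 Yki-Dam and 4568 Dam-Jra peaks, with median lengths of 771, 965.5 and 1042.5 bp. The deposited Dam-Sd fold changes followed those against all 9 Dam libraries (r = 0.933 across peaks) more closely than those against Set 1 (0.757). In the authors' deposited table the highest Dam-Sd peaks lay in adp (2R:18151688-18152150, log2 7.27), Gdi (2L:9494388-9494516, 7.24) and the phosphatase gene Ptp61F (3L:1393941-1394093, 6.84). The highest Yki-Dam peaks in the authors' deposited table lay at 3R:21735408-21735690 (7.68), in Ptp61F (6.68) and at 3R:15906730-15907287 (6.43). The highest Dam-Jra peaks there lay in the heat shock gene Hsp27 (3L:9384294-9384572, 9.93), apt (2R:23565534-23565972, 9.22) and Gpdh1 (2L:5944549-5944850, 9.05). For ex, the authors' deposited table put the top Dam-Sd and Yki-Dam peaks at the same place (2L:434810-435240, 4.18 and 3.92) and the top Dam-Jra peak at 2L:433156-434694 (4.17). In that Dam-Jra peak, the ends at 433164 and 434358 had mean CPM of 2.4 and 2.45 in Dam-Jra and 0.01 each in Dam of Set 3. The end at 434371 there had 14.56 and 5.5. In the Dam-Sd peak, the end at 434869 had 436 in Dam-Sd and 19.9 in Dam of Set 1. For puc, the authors' deposited table put the top Dam-Jra peak at 3R:8120295-8121421 (3.96) and those of Dam-Sd and Yki-Dam at 3R:8105569-8106365 (1.83 and 1.92).

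Hippo pathway targets held a deposited peak in 16 of 23 windows for Dam-Sd, 19 for Yki-Dam and 20 for Dam-Jra, where 26.5%, 20.9% and 26.9% of all windows did. AP-1 targets held a peak in 27, 23 and 26 of 32 windows and eye-antennal genes in 22, 23 and 24 of 31. Signalling genes did in 18, 16 and 19 of 23, so such shares were not particular to Hippo pathway targets. Of 31 ribosomal protein genes 8, 5 and 13 did, and of 30 chemosensory receptors 1, 2 and 4 did. Window length was not matched to that of all windows. Of the Yki-Dam peaks 76.02% overlapped a Dam-Sd peak, against 8.377% on average in shifted lists (permutation by shifts, p = 0.001, the smallest that 1000 shifts can give). Dam-Jra peaks overlapped Dam-Sd peaks in 57.46% (8.617% shifted), and Yki-Dam peaks overlapped Dam-Jra peaks in 66.12% (8.418% shifted), with the same p. With an overlap of 50% of both peaks required, the shares were 50.67%, 29.29% and 40.69%. The lists may share Dam libraries as controls, and the shifts do not allow for that. Genes listed with peaks were shared in 2266 cases by Dam-Sd and Yki-Dam (578.9 expected, Fisher's exact test, odds ratio 39.26), 2144 by Dam-Sd and Dam-Jra (701.1 expected, 14.47) and 2044 by Yki-Dam and Dam-Jra (559.7 expected, 23.71), and 1737 of 5185 genes were listed for all 3. A gene start lay inside 25.5% of Dam-Sd peaks, which were the shortest, 31.6% of Yki-Dam peaks (Fisher's exact test, two-sided, odds ratio 0.739 for Dam-Sd against Yki-Dam, adjusted p = 2.77e-10) and 31.3% of Dam-Jra peaks (0.748, adjusted p = 2.77e-10). Within 1 kb of a start the shares were 56.8%, 59.7% and 62.1%, and length was not matched in either count.

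**Figure D5:**
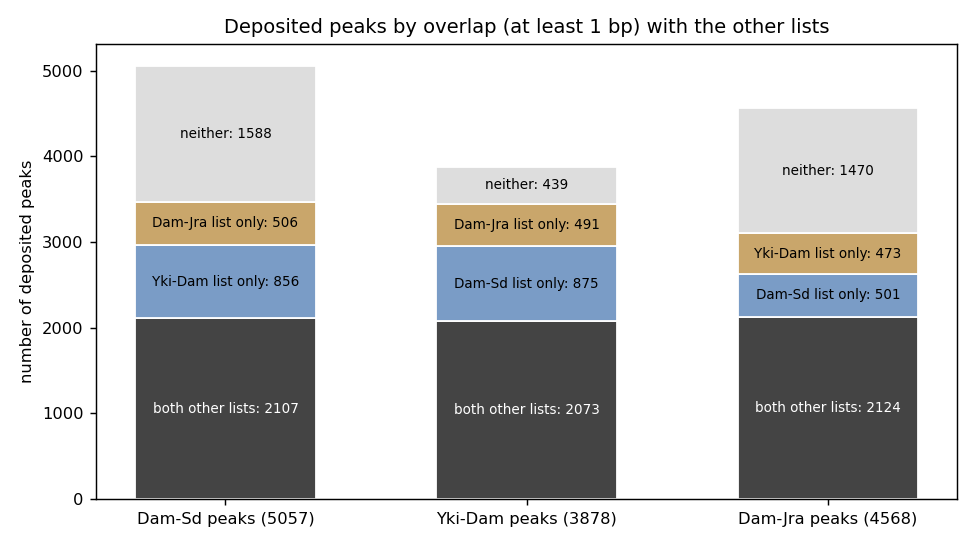
Bars count the deposited peaks of each fusion (y axis, number of peaks), divided by overlap of at least 1 bp with the lists of the other fusions (x axis, fusion). Peaks that overlapped both other lists numbered 2107 for Dam-Sd, 2073 for Yki-Dam and 2124 for Dam-Jra, and 1588, 439 and 1470 overlapped neither.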

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

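The test of a background shared with Set 1 and the test of a property of any fusion were chosen only after the result was seen, as were the interval added to the test without the strongest ends and the list tests with Set 3 as the control or an estimated correlation.

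Differences between fusions in their change against Dam drew attention, each past its own test of the difference. Between Dam-Sd and Yki-Dam, yki differed by log2 −1.38. Between Dam-Jra and Dam-Sd the differences were 1.81 for yki, 3.06 for Jra, −2.14 for ex, −1.38 for Diap1, −1.82 for mir-ban, 1.43 for puc and 1.72 for Mmp1. Between Dam-Jra and Yki-Dam they were 0.76 for sd, 3.25 for Jra, −1.22 for ex, −0.96 for Diap1, −1.59 for mir-ban, 1.55 for puc and 1.56 for Mmp1, of which sd did not pass with Set 3 as the control (0.13, edgeR adjusted p = 0.848). Jra in Dam-Jra, yki in Yki-Dam and sd in Dam-Sd are genes of the fused proteins, so their signal includes any reads from the transgene. Both JNK lists include Jra, and the Hippo pathway components list includes sd and yki. The counts and tests of these lists include the fused genes, and the lists were not tested without them. The log2 fold change of the median end inside the gene minus that around it was 4.26 for Jra. For sd and yki it was 0.92 and 0.61 in their own fusions and 1.90 and 0.73 in Dam-Jra, which carries neither, so it does not measure the transgene's part there. Among the lists, ribosomal proteins had a median difference of −0.49 between Dam-Sd and Yki-Dam and 0.70 between Dam-Jra and Dam-Sd. JNK pathway components had 0.49 between Dam-Jra and Dam-Sd and 0.12 between Dam-Jra and Yki-Dam. Actomyosin and cell shape genes and JNK pathway and AP-1 targets each had 0.14 between Dam-Jra and Yki-Dam. With Set 3 as the control the medians against Yki-Dam were −0.15 for AP-1 targets (camera adjusted p = 0.386), −0.09 for actomyosin genes (0.57) and −0.02 for JNK pathway components, which passed upward with a mean of 0.30 (0.0269). That mean includes Jra, which differed by 3.29 there. Against Dam-Sd, the Set 3 medians were 0.35 for ribosomal proteins (camera adjusted p = 0.0576) and 0.03 for JNK pathway components (0.154). With an estimated correlation none of these list differences passed (camera adjusted p of 0.414 between Dam-Sd and Yki-Dam, 0.487 and 0.885 between Dam-Jra and Dam-Sd, and 0.69 between Dam-Jra and Yki-Dam).

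Some ends called higher in a fusion had at most 3 reads in each Dam library of the comparison, 52 for Dam-Sd, 252 for Yki-Dam and 68 for Dam-Jra. Binding near the site is a candidate explanation, and ends of other sites within 2 kb were higher too, with a median log2 fold change of 1.47 (7150 ends). These ends can include the far end of the same stretch between GATC sites. Ends near other called ends were not measured for comparison, so this value cannot set binding apart from a strain variant. A strain variant that removes the GATC site in the Dam flies may account for part of them. The other end of the site also had at most 3 reads in each Dam library in 28.60% of 175 cases. That lies between the bounds of 20% and 50% set for that test. The shares were 0.05%, 0.37% and 0.04% at called ends with over 3 reads in each Dam library of the comparison. Those sites were chosen for having Dam reads, so their low shares were largely fixed in advance and do not favour a variant. Of the Dam-Sd and Yki-Dam ends with at most 3 reads in each Dam library of their comparison, 53.8% and 52.8% had over 3 reads in each library of another Dam set. Both explanations stay open.

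The deposited Dam-Jra fold changes followed the Set 3 Dam libraries (r = 0.949 across 4568 peaks, against 0.469 for Set 1), although the titles place Dam-Jra in Set 1, while those of Yki-Dam followed its own Set 2 (0.928) and those of Dam-Sd all 9 Dam libraries (0.933, and 0.757 for its own Set 1). A genetic background shared with the Set 1 flies was argued against: of 294 ends with at most 3 reads in each Set 1 Dam and Dam-Sd library and at least 30 in each other Dam library, 0.70% had at most 3 in each Dam-Jra library. A background shared with the Set 3 flies may hold: of 120 ends with at most 3 reads in each Set 3 Dam library and at least 100 in each Set 1 Dam library, 70.80% had at most 3 in each Dam-Jra library. The same share was 48.3% in Yki-Dam, 82.5% in Dam of Set 2 and 0.8% in Dam-Sd, so Sets 2 and 3 cannot be told apart as the source, and 21 of the 120 ends had at least 30 reads in each Dam-Jra library. A wrong set in the titles also stays open, and no biological explanation was tested.

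In Dam-Sd, Yki-Dam and Dam-Jra, 17, 19 and 21 of 23 Hippo pathway targets, 30, 27 and 31 of 32 AP-1 targets, 27, 26 and 28 of 31 eye-antennal genes and 16, 16 and 19 of 23 signalling genes were higher, and the lists passed camera with the preset correlation but not with an estimated one (adjusted p of 0.131 or more), though they passed with it when library size was the only scaling (adjusted p of 0.0483 or less). Window size and Dam level were argued against only as the whole cause: the lists' medians lay at or above percentile 99.25 of 10000 random lists matched on both, whose own medians were 0.44 to 0.98, such as 0.95 beside 1.45 for AP-1 targets in Dam-Sd. A property of any fusion stays open, since 41.70% of the 103 members differed between Dam-Jra and Dam-Sd (45.6% with Set 3) but so did 40.7% of all windows (29.4%), and edgeR called 0 members between Dam-Sd and Yki-Dam (17 at an unadjusted p under 0.05). A few ends taking most reads may carry part of it. The smallest share of a median kept without the top 1% of ends was 76.10% (signalling genes in Dam-Sd), past the bound of 75% set for that test. Its interval of 57.5% to 112.9% reaches below that bound. The interval with the lowest limit, 45.0% to 113.1%, was that of signalling genes in Yki-Dam. No biological explanation was tested.

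Other divisions of the same libraries were counted for each comparison. For 3 libraries against 3 the 10 divisions are too few for a share under 0.05, and 1 of them, the real one, gave as many calls. The real and the highest other counts of windows were 7946 and 6 for Dam-Sd, 5955 and 27 for Yki-Dam, 507 and 170 for Dam-Sd against Yki-Dam, 5741 and 1 for Dam-Jra against Dam-Sd and 3502 and 0 for Dam-Jra against Yki-Dam. The counts of ends were 112774 and 3761 for Dam-Sd and 63631 and 2960 for Yki-Dam. Each of these other divisions mixes libraries of both groups, so a real difference adds to the fitted spread and holds their calls down. Their low counts therefore add no support for the real ones. For Dam-Sd and for Yki-Dam the real divisions part all 3 replicate pairs of the fusion with its Dam set. The others that do so gave at most 0 calls, and the remaining ones keep some pairs together. For Dam-Sd against Yki-Dam, divisions that part equal replicate numbers gave at most 55 calls besides the real one. Those numbers come from Sets 1 and 2 and no pairing was shown between them, so the 55 says nothing about pairs. For Dam-Jra 1 of 100 divisions was as large for windows (9715, highest other 6994), 1 of 40 for ends (164761 and 89626) and 1 of 40 for ends called against both candidate sets (58217 and 26686). These shares are under 0.05, but the divisions treat the Dam sets as interchangeable. The highest other ones set the Set 1 Dam libraries apart, with the Dam-Jra libraries in the place of Set 1 among the controls. Their calls can come from the Dam-Jra signal as well as from differences between Dam sets, and these were not separated. The divisions that keep every set whole are 4 (9715 windows for Dam-Jra, and 6994, 6932 and 1463 for Sets 1, 2 and 3), too few for a share under 0.05. In those for a Dam set, the Dam-Jra libraries likewise took that set's place among the controls.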

How the results depend on the processing

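Fits without the 1 kb flanks, on windows that share no end, with Set 3 as control or with blocks for the gene lists, with an estimated correlation, and gene overlaps from windows with a peak, were tests chosen only after the result was seen. Among other settings for counts and shares, 80 of 117 values stayed within 1.5 times or within their limits, and among named genes and lists 2248 of 2323 kept direction and call, 53 lost the call, 2 gained it and 20 reversed. Each cause was not tested except where given.

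With adjusted p below 0.01 the windows called were 3571 for Yki-Dam, 50 for Dam-Sd against Yki-Dam, 3457 for Dam-Jra against Dam-Sd and 1660 against Yki-Dam, and the ends 60905, 24716 and 92013 for Dam-Sd, Yki-Dam and Dam-Jra. With a change above 2-fold they were 4926, 2786 and 5854 windows, and 2239 for Dam-Jra against Yki-Dam. With library size as the only scaling Yki-Dam gave 10083 windows and 132059 ends, Dam-Sd 180537 ends and Dam-Jra 92768 ends against both sets. That scaling reversed Jra (−0.44), Mmp1 (−0.50), brp (−0.33), cpx (−0.38), Syx1A (−0.23), nrv2 (−0.06) and osk (−0.15) in Dam-Sd, Jra (−0.36), Mmp1 (−0.05), Tm2 (−0.09) and osk (−0.01) in Yki-Dam, and Eaat2 (−0.12) and twi (−0.27) in Dam-Jra.

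With the replicate block 2050 windows were called for Dam-Sd against Yki-Dam, 5599 for Dam-Jra against Yki-Dam and 95916 ends for Yki-Dam, and with the block and Set 3 as the control together 100310 ends for Dam-Jra. Of 345 values of named genes and lists the block changed the call of 1, the glia list of Dam-Sd (0.0504), and of the windows called without it it kept 9372 of 9715 for Dam-Jra, 5413 of 5741 for Dam-Jra against Dam-Sd and 3417 of 3502 against Yki-Dam. With the fusions compared directly 2171 and 6232 windows differed from Yki-Dam in Dam-Sd and Dam-Jra. With Set 3 as the control Dam-Jra gave 68959 ends and 1260 windows against Yki-Dam, and r was 0.4979 with Dam-Sd and 0.6625 with Yki-Dam. Yki-Dam gave 105453 ends against the mean of the 3 Dam sets and 22568 with only its own comparison's libraries fitted. DESeq2's Wald test gave 1250 windows for Dam-Sd against Yki-Dam. Without the flanks these were 328, and RpL8 (−1.06) and RpS9 (−0.39) in Dam-Sd, His2Av (−0.34) and osk (−0.13) in Yki-Dam and RpLP0-like (−0.06), Cka (−0.19) and osk (−0.72) in Dam-Jra reversed, as only flanking ends had been left out. Windows that share no end gave 619, 520 and 1035 calls, since only 1409 were tested, and r across 1410 was 0.7487 for Dam-Sd and Yki-Dam, 0.7512 for Yki-Dam and Dam-Jra and 0.5717 for Dam-Sd and Dam-Jra. With an estimated correlation and TMM scaling 0 lists were called by camera, with an unadjusted p as low as 0.0058 (JNK pathway components, Dam-Jra), and with library size as the only scaling 20 were, 5, 7 and 8 in Dam-Sd, Yki-Dam and Dam-Jra.

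Leaving out 1 library at a time gave 6701 to 8697 windows for Dam-Sd, 4858 to 6300 for Yki-Dam, 8552 to 9914 for Dam-Jra, 164 to 2616 for Dam-Sd against Yki-Dam, 4340 to 6037 for Dam-Jra against Dam-Sd and 2225 to 3726 against Yki-Dam. It gave 69166 to 127922 ends for Dam-Sd, 36852 to 60300 for Yki-Dam, 98733 to 176341 for Dam-Jra and 28372 to 56956 against both sets. Of 99 such counts 77 stayed within 1.5 times and 22 moved further. Counts moved over 1.5 times for Dam-Sd ends without Dam replicate 3 of Set 1 (73812) or Dam-Sd replicate 1 (69166), for Yki-Dam ends without Yki-Dam replicate 2 (36852) or 3 (38825) and for Dam-Jra ends without Dam-Jra replicate 2 (102562) or 3 (98733). The other moves, given with the results above, were in windows of Dam-Sd and of Dam-Jra against Yki-Dam and in ends against both sets. Of 1878 values of named genes and lists, 1861 kept direction and call, 15 lost it and 2 gained it. Windows around gene starts and motif settings were not run. Simulated 4-fold changes were called in 21.3% of changed ends and 100% of changed windows for Dam-Sd. Ends had lower counts and a larger simulated dispersion (0.308 against 0.0494), and these were not separated.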

Other observations

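The mthl8 window was chosen only after the result was seen, with no tests run on it, and the ends are those with the smallest edgeR p of each comparison with Dam.

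The window of mthl8 (3L:22428-26308), a gene of the methuselah-like receptor family, shares no end with another window and had 0 reads in each Set 1 Dam library and in each Dam-Sd library, which allows up to 3 reads in each. It held 383 to 451 reads in Yki-Dam, 644 to 807 in Dam of Set 2, 711 to 846 in Dam-Jra and 865 to 1191 in Dam of Set 3 (n = 3 each).

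The end at 3L:733519 held 2389 to 3006 reads in Dam-Jra and 2324 to 3724 in Yki-Dam, against at most 4 in any Dam library and at most 2 in Dam-Sd. The end at 2L:7005496 in uif, a gene of an apical transmembrane protein, held 431 to 482 reads in Dam-Jra and 1307 to 2126 in Yki-Dam, against at most 5 in the other groups. The end at 2L:8086841 in Bsg held 646 to 899 reads in Dam-Jra and 517 to 1078 in Yki-Dam, and the end at 3R:15906227 held 502 to 731 reads in Yki-Dam. The end at 3R:30259306 held 1702 to 3001 reads in Dam-Sd, 449 to 684 in Yki-Dam and 131 to 158 in Dam-Jra, against 8 to 29 in the Dam libraries. In syd, the end at 3L:7935327 held 1 read in each Set 1 Dam library and 85 to 121 in Dam-Sd, but 117 to 511 in the other Dam sets. In CG1136, the end at 3L:4049894 held 12 to 22 reads in Set 1 Dam and 1525 to 2114 in Dam-Sd, against 175 to 690 in the other Dam sets.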
